A study of Homo sapiens with 18 samples.

How the data were processed

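RNA-seq was available for 18 libraries from 3 human lymphoma cell lines, SUDHL6, Farage and SUDHL4. Each line had 3 libraries of cells given DMSO, the vehicle, and 3 of cells given a BCL6 inhibitor, known by a code name, at 10 µM for 12 h. Groups and replicate numbers were taken from the labels. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

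The values are CPM, counts scaled to reads of the whole library, for 23250 gene symbols per library, as deposited. Reads were aligned with STAR to hg19, per the submitters' processing notes. Libraries were made with a TruSeq RNA kit, per the labels. A label of 1 sample also names Rsubread, and the names of the deposited files say RefSeq. The release of that annotation, the strand setting of the counting and the versions of these tools are not given in the sources used here. Each library's CPM values were whole multiples of the value of 1 read, so whole reads could be recovered: 100% of the values came out whole within a tolerance of 0.01 reads. The sum of the listed genes was 74.63 to 80.72% of the divisor of the CPM, so the divisor also held reads outside the listed genes. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and HSPA1A and HSPA1B, a near-identical pair, share reads.

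The main test was limma 3.58.1 in R 4.3.3, with an intensity trend in the variance, on log2(CPM + 1), where the pseudocount of 1 makes fold changes of weakly expressed genes smaller than the change in CPM. CPM were used as deposited with no further scaling. Genes with a CPM of at least 1 in at least 3 of the 18 libraries were tested, 12769 in all. A single model with a mean for each of the 6 groups gave 12 residual degrees of freedom. It shares 1 spread per gene across the lines. A line of wider spread can therefore get smaller p-values than alone, and the other lines larger ones. Replicates of SUDHL6 agreed least, with a chi-square per degree of freedom of 16.35 to 53.65. Its contrasts were treated against DMSO in each line, the mean of the 3 lines, the difference of the response for each pair of lines, and an F-test of any difference among the lines. All tests were two-sided with Benjamini-Hochberg adjustment, and a gene was called higher or lower at an adjusted p threshold of 0.05. Changes are log2 fold changes with the SE of the model, and levels are mean CPM ± SD of n = 3 libraries per group. Overlaps of calls between lines were tested with one-sided Fisher's exact tests; the lines have separate DMSO libraries.

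Before the data were examined, 33 gene lists with 730 members were fixed. All 730 were found, 12 of them by an older symbol. The 30 lists with at least 5 tested members were tested with camera of limma at a preset inter-gene correlation of 0.01, and adjusted over 120 tests (30 lists, 3 lines and their mean). Beside each stands the adjusted p with the correlation estimated from the data, under which none of the list calls held. With that setting camera also uses the 12 residual degrees of freedom in place of those from the number of genes. Its p-values are therefore larger for that reason too, not through the correlation alone. Members were counted as higher or lower over all genes tested; counts adjusted over the list alone were the same unless given. Lists share members: for example, SESN2 is in the p53 and ATF4 lists, NQO1 in the NRF2 and aryl hydrocarbon receptor lists, BCL2L11 in the BCL2 family and FOXO lists, BCOR in the PRC1 and corepressor lists, and SLC7A11 in the ATF4 and NRF2 lists.

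The genes named were also fixed by rule beforehand. BCL6, EZH2, CBX8 and BCOR are always given. In the mean of the lines, the 12 largest positive and 12 largest negative called changes are named, if of the same sign in all 3 lines and at a mean of at least 2 CPM. In each line the rule takes the 6 largest called changes per direction whose treated and DMSO values do not overlap, at a mean of at least 2 CPM over its 6 libraries; chance gives such separation to 10% of genes. Each list gives up to 4 members called in the mean, smallest p first. Each pair of lines gives the 3 called differences of smallest p. Unnamed loci were skipped in these rankings. Lists of other cell types are given as lists with at most 2 examples of the largest CPM. The rule took 165 genes, summarised where they are many, and single values of a few of them are not reported. Genes outside it are marked as chosen after their values were seen.

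Alternatives were a pseudocount of 0.25, no filter (19369 genes), a mean CPM of at least 5 (9678 genes), median-of-ratios scaling, a term for each line and replicate number (6 residual degrees of freedom), only the compared lines in the fit, a fold of at least 1.5, each library left out in turn, and tests on the recovered reads with edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0. Chosen after seeing the data were a fit without both shallow SUDHL6 libraries, camera on the differences between lines, shuffles of the line labels for the number of genes that differ, and a comparison of the DMSO libraries of Farage with those of the other lines. Replicate numbers were taken from the labels. Deviations of same-numbered treated and DMSO libraries from their group means correlated at 0.42, 0.49 and 0.63 in SUDHL6, so the numbers pair its samples; in Farage (0.17, -0.13 and -0.19) and SUDHL4 (-0.05, 0.03 and -0.07) they do not.

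The tests were checked on simulated reads drawn from the means and depths of these libraries (12448 genes in the fit). For the comparison of SUDHL6, limma recovered 83.6% of 61 genes changed 2-fold and 12.4% of its 170 calls were false. For Farage these were 86.9% and 8.33%, for SUDHL4 82% and 7.36%, and for the mean of the lines 100% and 5.18%. Of 65 genes changed 1.5-fold, 50.8%, 53.8% and 50.8% were recovered in SUDHL6, Farage and SUDHL4 and 80% in the mean. The share of false calls in a single line therefore lay above the nominal 5% in the simulation. With edgeR it was 3.9%, 4.43% and 3.85% in SUDHL6, Farage and SUDHL4. Only 65, 61 and 70 genes were changed in the simulation, by 1.5-fold, 2-fold and 4-fold. In the data 68.1 to 83.9% of genes were called in a line or in the mean. The simulated recovery and shares of false calls therefore need not carry over to the real calls.

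GENCODE and RefSeq tables of GRCh38 served only for gene names, GC content, transcript length (both for 12242 genes, 95.9% of those tested) and genomic span (12330 genes, 96.6%). They differ in build from hg19, so no coordinates are given. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.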

Results

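RNA was sequenced from 3 human diffuse large B cell lymphoma lines, SUDHL6, Farage and SUDHL4, after 12 h with DMSO or with an inhibitor of BCL6 at 10 µM. BCL6 is a transcriptional repressor of the germinal centre B cell that acts through corepressors such as BCOR. EZH2 is the methyltransferase of Polycomb repressive complex 2 (PRC2), and CBX8 is a chromodomain subunit of Polycomb repressive complex 1 (PRC1). The series concerns cooperation of BCL6 with EZH2 in a Polycomb complex that holds CBX8 and BCOR. These libraries address which genes change when BCL6 is inhibited. There were 6 groups of 3 libraries. The listed genes held 7.36 to 20.6 M reads per library in SUDHL6 DMSO and 6.29 to 17.35 M in treated SUDHL6, where the low ends are replicate 3 of each group. They held 21.83 to 24.1 M in Farage DMSO, 20.22 to 23.35 M in treated Farage, 22.1 to 25.49 M in SUDHL4 DMSO and 16.87 to 22.55 M in treated SUDHL4. In the shallowest library 3 reads correspond to 0.362 CPM.

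The first principal component (43.6% of the variance of log2(CPM + 1)) set Farage apart from SUDHL6 and SUDHL4. In each line the treated libraries lay above the DMSO libraries on both PC2 (27.1%) and PC3 (22%). SUDHL4 DMSO replicate 3 lay nearer to the treated libraries than its partners, at 34.4 on PC2 against 24 and 23.4. Treated SUDHL6 replicate 1 lay apart from its partners, at -9.5 against -31.5 and -27.2. No libraries were duplicates. Read counts of replicates differed with a chi-square per degree of freedom of 1.86 to 53.65 for pairs within a group, and their log2 values correlated at 0.9734 to 0.9986 across genes.

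**Figure D1:**
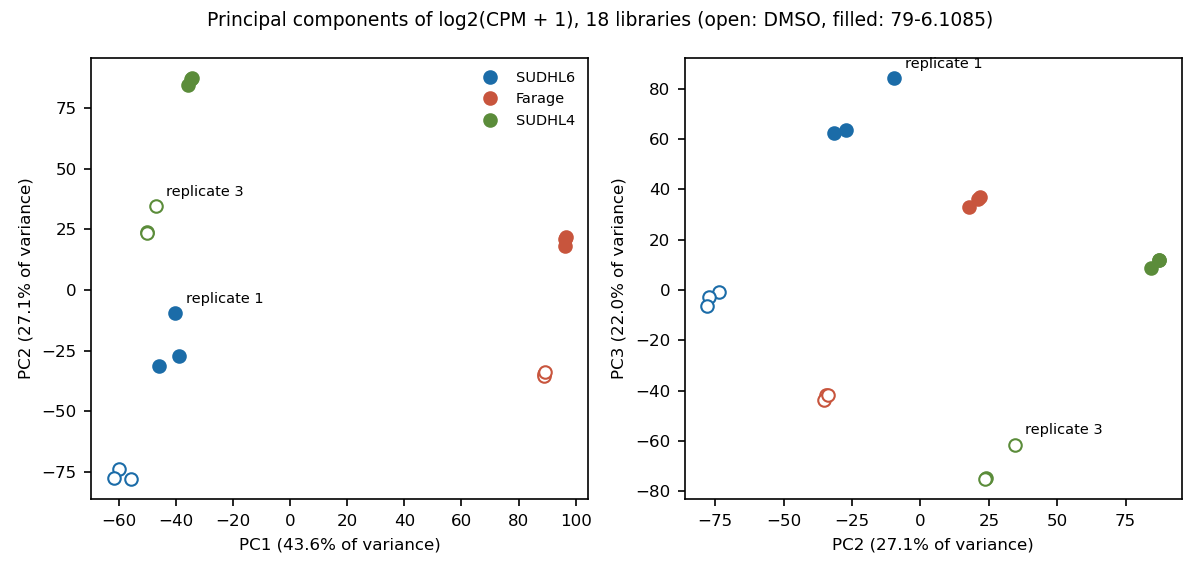
PC1 against PC2 (left) and PC2 against PC3 (right) of log2(CPM + 1), 1 point per library, coloured by line, open for DMSO and filled for the inhibitor. PC1 (43.6% of the variance) separates Farage, and treated libraries lie higher on PC2 and PC3.

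BCL6 itself fell in SUDHL4, from 497.2 ± 33 to 233 ± 5.57 CPM (log2 fold change -1.09, SE 0.144, adjusted p = 4.14e-06, n = 3), and in SUDHL6, from 325.4 ± 75.4 to 255 ± 59.7 CPM (-0.35, adjusted p = 0.0409). In Farage it was at 204.8 ± 1.86 and 211.1 ± 10.9 CPM (0.04, adjusted p = 0.814). BCOR fell in Farage from 72.53 ± 1.67 to 15.35 ± 2.53 CPM (-2.18, adjusted p = 2.32e-09) and in SUDHL4 from 56.49 ± 5.69 to 36.73 ± 6.77 CPM (-0.62, adjusted p = 0.00125). In SUDHL6 it was at 75.87 ± 9.92 and 78.73 ± 12.9 CPM (0.05, adjusted p = 0.799). CBX8 fell in Farage from 3.748 ± 0.411 to 0.9516 ± 0.28 CPM (-1.29, adjusted p = 3.79e-06) and in SUDHL4 from 13.96 ± 1.35 to 5.874 ± 0.415 CPM (-1.12, adjusted p = 1.69e-05). In SUDHL6 it was at 13.91 ± 2.05 and 11.08 ± 3.22 CPM (-0.33, adjusted p = 0.0948). EZH2 was not called in any line. Its levels in DMSO and treated libraries were 129.7 ± 18.5 and 121 ± 44 CPM in SUDHL6 (-0.15, adjusted p = 0.443), 59.88 ± 0.756 and 65.29 ± 1.1 in Farage (0.12, adjusted p = 0.519), and 105.8 ± 2.31 and 128 ± 6.65 in SUDHL4 (0.27, adjusted p = 0.149). In the mean of the lines BCL6 changed by -0.47 (SE 0.0833, adjusted p = 6.63e-05), BCOR by -0.92 (SE 0.0847), CBX8 by -0.91 (SE 0.0975) and EZH2 by 0.08 (adjusted p = 0.423). The BCL6 call in SUDHL6 was lost with median-of-ratios scaling (-0.17, adjusted p = 0.243), edgeR (adjusted p = 0.293), DESeq2 (0.249), no filter (0.065) and only that line in the fit (0.251). It held with the replicate block (adjusted p = 0.00108), whose numbers pair the samples in this line: BCL6 was lower in each pair, at 305 and 214, 409 and 324, and 262 and 227 CPM. Leaving out 1 library ended it for SUDHL6 DMSO replicate 1 (0.0524) or 2 (0.264), treated SUDHL6 replicate 1 (0.178) or 3 (0.13), Farage DMSO replicate 1, 2 or 3 (0.0501 each) or treated SUDHL4 replicate 1 (0.0502). EZH2 was called higher in the mean with median-of-ratios scaling (0.32, adjusted p = 0.00476), edgeR (0.00213) and DESeq2 (0.000929). In SUDHL6 it was called lower without treated replicate 3 (-0.42, adjusted p = 0.00117), and CBX8 without treated replicate 2 (-0.52, adjusted p = 0.00847). With the replicate block CBX8 was not called in SUDHL6 (adjusted p = 0.051). It was lower in each pair, at 12.8 and 7.92, 16.3 and 14.3, and 12.6 and 11 CPM.

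In SUDHL4, EZH2 was called higher with median-of-ratios scaling (0.57, adjusted p = 0.00509), edgeR (0.00264), DESeq2 (0.00137), only that line in the fit (0.00248) and without treated SUDHL6 replicate 3 (0.0109), whose removal changes the spread shared by all groups. In Farage it was called higher with edgeR (0.37, adjusted p = 0.0473), DESeq2 (0.0424) and only that line in the fit (0.0112). DESeq2 also called BCL6 higher there (0.30, adjusted p = 0.0414).

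**Figure D2:**
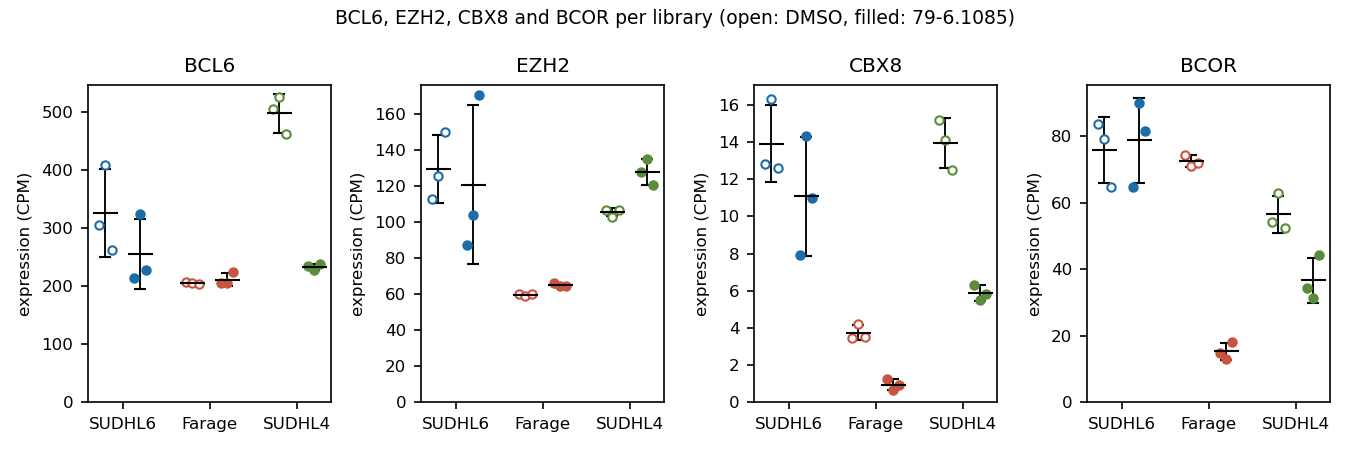
Expression of BCL6, EZH2, CBX8 and BCOR in CPM, 1 point per library (open for DMSO, filled for the inhibitor), with the mean and SD of each group of 3. BCL6 fell most in SUDHL4 (497.2 to 233 CPM) and BCOR in Farage (72.53 to 15.35 CPM).

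Averaged over the 3 lines, the 12 genes that rose most have varied functions. DNAJB4, a cochaperone of HSP70, rose by 4.60 (SE 0.213, adjusted p = 6.88e-12). It went from 6.306 ± 0.373 to 182.5 ± 64.3 CPM in SUDHL6, 7.487 ± 0.431 to 327.4 ± 25.9 in Farage and 22.5 ± 19.8 to 287.8 ± 42 in SUDHL4. SLC7A11, the cystine transporter, rose by 4.27 (8.978 ± 1.79 to 261.7 ± 106 CPM in SUDHL6), and SQSTM1, an autophagy receptor, by 3.75 (251.4 ± 13.7 to 2052 ± 167 CPM in Farage). The other 9 of the 12 were OSGIN1 (4.43), the stress factor ATF3 (4.30), the surface receptor SLAMF7 (4.09), HSPA1B (3.92, sharing reads with HSPA1A), the cochaperone BAG3 (3.76), RGS1 (3.71), the autophagy gene GABARAPL1 (3.68), GCLM of glutathione synthesis (3.63) and KLHL21 (3.60). The DMSO libraries of SUDHL4 spread widely for these genes (OSGIN1 1.603 ± 2.3 CPM). Replicate 3 of that group held a median of 16.22% of the treated-minus-DMSO change over 718 genes changed at least 4-fold in that line. Without it 3810 genes were higher and 6812 lower in the mean of the lines, against 3842 and 6876 with it.

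The genes that fell most in the mean were NAPSB (-3.27, SE 0.103, adjusted p = 2.2e-13), LRRC20 (-3.15), PTPN6 (-3.12), MRM1 (-3.09), IKBKE (-3.00), ALDH1B1 (-2.99), PFAS (-2.98), SIT1 (-2.94), CDCA7 (-2.94), RSAD1 (-2.91), CUX2 (-2.88) and ELL3 (-2.83). PTPN6 codes for a phosphatase of antigen receptor signalling and went from 336.4 ± 39.2 to 23.25 ± 1.25 CPM in SUDHL4. PFAS, an enzyme of purine synthesis, went from 167.1 ± 14.8 to 25.67 ± 4.94 CPM in SUDHL6, 96.43 ± 2.41 to 13 ± 0.673 in Farage and 80.18 ± 10.8 to 6.357 ± 0.801 in SUDHL4. Of the 12769 genes tested, 83.9% were called in the mean, 776 of them higher and 2039 lower by at least 2-fold. The median change over all genes was -0.238 at the deposited scale (-0.129 in SUDHL6, -0.224 in Farage and -0.213 in SUDHL4), so a gene at 0 lies above the typical gene. With median-of-ratios scaling 5033 genes were higher and 5664 lower, 47.1% higher against 35.8% at the deposited scale. On the recovered reads edgeR called 4996 higher and 5123 lower.

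**Figure D3:**
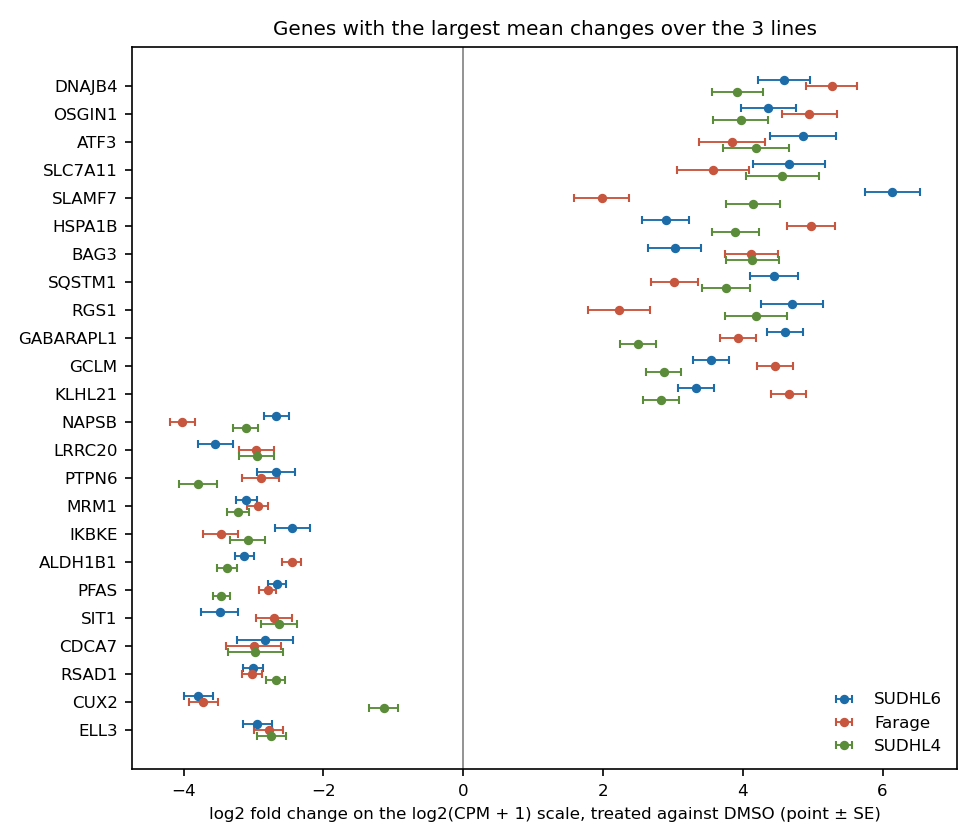
Log2 fold changes on the log2(CPM + 1) scale, treated against DMSO, of the 24 genes with the largest mean changes, 1 point ± SE per line. The 12 that rose run from DNAJB4 (mean 4.60) to KLHL21 (3.60) and the 12 that fell from NAPSB (-3.27) to ELL3 (-2.83).

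Lists of stress responses rose in the mean of the lines. With the treatment labels shuffled within lines, camera at the preset correlation called a median of 9 lists in the mean, and at most 17. The real labels gave 13, so a call at that setting does not by itself set treatment apart. Of 26 tested members of the ATF4 amino acid response, 24 rose and 1 fell (median 1.27, camera adjusted p = 4.14e-10; adjusted p = 0.309 with an estimated correlation). Those that rose include the amino acid transporter genes SLC7A5 (1.64) and SLC3A2 (2.19), SESN2 (2.10) and CTH of cysteine synthesis (3.10). Of 16 NRF2 response members, 14 rose and 2 fell (median 2.09, adjusted p = 6.29e-07; adjusted p = 0.309 with an estimated correlation). They include SRXN1 (2.64), NQO1 (3.23) and the ferritin light chain FTL (2.22). Of 15 heat shock members 12 rose and none fell (median 1.42, adjusted p = 6.29e-07; adjusted p = 0.343 with an estimated correlation). They include HSPA1A (2.45), DNAJB1 (2.74), AHSA1 (1.42) and STIP1 (1.29). Of 20 glycolysis and hypoxia members 16 rose and none fell (median 0.66, adjusted p = 1.95e-06; adjusted p = 0.309 with an estimated correlation). They include VEGFA (2.71), KDM3A (1.92), BNIP3L (1.93) and P4HA1 (1.82). Of 24 immediate early genes 18 rose and 4 fell (median 1.03, adjusted p = 3.63e-05; adjusted p = 0.343 with an estimated correlation). They include FOSB (3.18), DUSP1 (2.66) and DUSP5 (3.57). NR4A2 (0.95) rose in Farage (2.80) and was near 0 CPM elsewhere.

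Smaller lists also rose. Of 12 histone genes 10 rose and 1 fell (median 0.78, adjusted p = 0.000476; adjusted p = 0.313 with an estimated correlation). They include HIST1H2BD (1.76), HIST1H2BK (1.002) and HIST2H2BE (1.18). HIST1H4C (0.93) rose mostly in SUDHL6 (2.40, at 5.31 ± 0.81 CPM). It and several other histone members stayed under 1 CPM in both groups of Farage and of SUDHL4, where their changes rest on few reads. All 6 members of the aryl hydrocarbon receptor list rose (median 0.51, adjusted p = 0.00348; adjusted p = 0.309 with an estimated correlation). They include TIPARP (1.42). Of its enzymes CYP1B1 rose in Farage (1.26) and CYP1A1 in SUDHL4 (1.44), and in the mean CYP1B1 was not called with edgeR (adjusted p = 0.0556) or DESeq2 (0.0558). Of 12 FOXO targets 7 rose and 3 fell (median 0.72, adjusted p = 0.0391; adjusted p = 0.444 with an estimated correlation). SESN1 (0.99), the proapoptotic BCL2L11 (1.40) and IRS2 (1.61) rose and TXNIP (-1.37) fell, where IRS2 was not called with edgeR (adjusted p = 0.0563). The FOXO call was lost with median-of-ratios scaling (0.0792), at a mean CPM of at least 5 (0.107), without SUDHL6 DMSO replicate 3 (0.0678) and without both shallow SUDHL6 libraries (0.0523). The list's medians in these settings were 0.944, 0.721, 0.666 and 0.716.

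Lists of proliferation and B cell receptor signalling fell. All 18 MYC targets and genes of ribosome biogenesis fell (median -1.15, adjusted p = 5.58e-05; adjusted p = 0.343 with an estimated correlation). They include MYC itself (-1.83), the pyrimidine synthesis gene CAD (-2.55), DKC1 (-1.41) and MYBBP1A (-2.19). Of 22 DNA replication genes 20 fell and none rose (median -1.52, adjusted p = 0.000581; adjusted p = 0.62 with an estimated correlation). They include CDC45 (-1.42), MCM3 (-1.85), POLA1 (-2.25) and UNG (-2.38). Of 22 mitosis genes 21 fell and none rose (median -1.54, adjusted p = 0.0078; adjusted p = 0.762 with an estimated correlation). They include CCNB1 (-1.80), CCNA2 (-1.88), AURKB (-2.15) and BUB1B (-2.10). Of 36 oxidative phosphorylation genes 31 fell and none rose (median -0.49, adjusted p = 0.000486; adjusted p = 0.578 with an estimated correlation). With median-of-ratios scaling, which centres the typical gene, their median was -0.25. They include NDUFV1 (-1.52), ATP5C1 (-1.27), UQCRQ (-1.22) and ATP5A1 (-0.96). Of 21 genes of B cell receptor signalling 19 fell and 2 rose (median -1.24, adjusted p = 0.00327; adjusted p = 0.578 with an estimated correlation). Kinase gene BTK (-1.62), PLCG2 (-1.29) and the receptor chain CD79B (-1.69) are among those that fell.

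**Figure D4:**
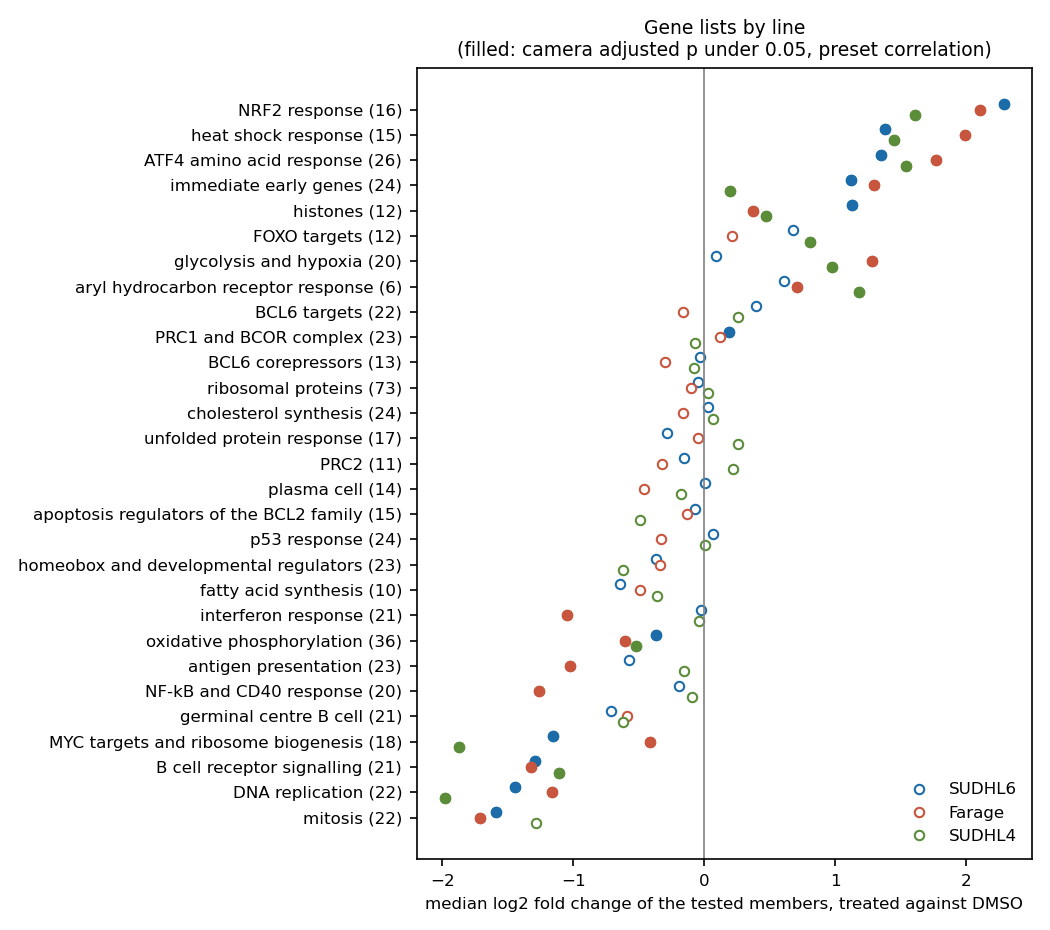
Median log2 fold change of the tested members of each gene list, 1 point per line, with the number of tested members in brackets; filled points have a camera adjusted p under 0.05 at the preset correlation. The ATF4, NRF2 and heat shock lists lie highest in all 3 lines, mitosis lowest in SUDHL6 and Farage, and DNA replication lowest in SUDHL4, where mitosis is open (adjusted p = 0.0794).

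The lists nearest to the question of BCL6 and Polycomb were not called in the mean. Of 22 BCL6 targets 11 rose and 6 fell (median 0.20, adjusted p = 0.0985). The acetyltransferase EP300 rose in each line (1.02 in SUDHL6, 0.99 in Farage, 0.99 in SUDHL4), as did CD69 (mean 1.44), while CCND2 (-0.82) fell. Of 21 germinal centre B cell genes 14 fell and 3 rose (median -0.68, adjusted p = 0.294), with the transcription factor SPIB (-2.32), STAP1 (-0.83), SERPINA9 (-0.86) and ELL3 lower. Of 14 plasma cell genes 5 rose, such as SLAMF7, and 7 fell, such as MZB1 (-2.49), CD38 (-1.26) and FKBP11 (-1.16). Their median (-0.21) and mean (-0.03) lay below 0 and the test pointed up (adjusted p = 0.91). Of 11 PRC2 genes 4 rose and 5 fell (median -0.10, test upward, mean -0.26, adjusted p = 0.707). PHF1 rose (1.36), and the histone-binding RBBP7 (-1.39) and RBBP4 (-1.01) and PHF19 (-2.16) fell. Of 23 genes of PRC1 and the BCOR complex 11 rose and 9 fell (median 0.04, adjusted p = 0.115). RYBP (1.92) and PHC3 (1.05) rose and CBX7 (-2.03) fell. Of 13 BCL6 corepressors 4 rose, such as TBL1X (0.73), and 5 fell, such as CTBP1 (-0.62) and HDAC7 (-1.07). Their median was 0.03, their mean -0.14 and the test pointed up (adjusted p = 0.748). Of 23 homeobox and developmental regulators, a class of Polycomb targets, 18 fell and 2 rose (median -0.36, adjusted p = 0.12). They include HOXA3 (-1.37), HOXB4 (-1.15) and HOXB3 (-0.89), and HOXA10 (-0.47), above 1 CPM in Farage alone (6.179 ± 0.182 to 1.657 ± 0.175 CPM). In the mean HOXA10 was not called with edgeR (adjusted p = 1) or DESeq2 (0.048, adjusted p = 0.959). The medians of the plasma cell and PRC2 lists move to 0 and 0.14 and that of the corepressors to 0.27 with median-of-ratios scaling. Those of the BCL6 target and PRC1 and BCOR lists move to 0.36 and 0.28. Those of the germinal centre and homeobox lists move to -0.44 and -0.25.

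Immune lists were not called in the mean. Of 20 NF-kB and CD40 response genes 15 fell and 2 rose (median -0.61, adjusted p = 0.182), with FAS (-1.05), TRAF1 (-1.35) and TNFAIP2 (-0.80) lower and CCR7 (2.75) higher. TNFAIP2 was not called with edgeR (adjusted p = 1) or DESeq2 (0.21). Of 23 antigen presentation genes 15 fell and 4 rose (median -0.52, adjusted p = 0.149), such as HLA-DMB (-2.38), HLA-DPA1 (-0.96) and the immunoproteasome genes PSMB9 (-2.26) and PSMB8 (-2.03). Of 21 interferon response genes 15 fell and 2 rose (median -0.48, adjusted p = 0.141), such as MX2 (-0.97), XAF1 (-1.01) and IFIH1 (-0.52). With edgeR, XAF1 (adjusted p = 0.108) and IFIH1 (0.0556) were not called. The last 2 lists were called with no filter (0.0306 and 0.025).

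Members of the remaining lists moved both ways. Of 24 p53 response genes 10 rose, such as SESN2, and 13 fell, such as AEN (-1.95), FDXR (-1.87) and BTG2 (-1.12). Their median was -0.23, the mean -0.05 and the test upward (adjusted p = 0.699). Of 15 regulators of apoptosis of the BCL2 family 5 rose, such as BCL2L11, PMAIP1 (2.17) and MCL1 (0.40), and 8 fell, such as the antiapoptotic BCL2L1 (-1.61). Their median was -0.21, the mean 0 and the test upward (adjusted p = 0.693). Of 17 unfolded protein response genes 7 rose, such as DNAJC3 (1.56) and DNAJB9 (1.37), and 6 fell, such as PDIA4 (-1.30) and SDF2L1 (-2.06). Their median was -0.06, the mean 0.04 and the test upward (adjusted p = 0.405). Of 24 cholesterol synthesis genes 10 rose, such as INSIG1 (0.80), and 11 fell, such as ACAT2 (-1.28) and TM7SF2 (-1.19). Their median was -0.05, the mean -0.11 and the test upward (adjusted p = 0.46). Of 10 fatty acid synthesis genes 8 fell, such as ELOVL6 (-1.57), FADS1 (-1.39) and ACLY (-0.62), and ELOVL5 (0.46) rose (median -0.41, adjusted p = 0.316). Under median-of-ratios scaling the medians were -0.01 for p53, 0.03 for the BCL2 family and 0.18 for the unfolded protein response. They were 0.2 for cholesterol and -0.17 for fatty acid synthesis.

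Of 73 ribosomal protein genes 5 rose and 11 fell (4 and 5 adjusted over the list alone; median -0.05, mean -0.06, test upward, adjusted p = 0.386), with RPL17 (-0.59), RPS26 (-0.43), RPL41 (-0.26) and RPL35 (-0.32) lower. With median-of-ratios scaling the list's median was 0.19 and it was called higher (adjusted p = 0.0208), while RPL41 and RPL35 were not called (adjusted p = 0.643 and 0.394), nor were they with edgeR (0.835 and 0.517) or DESeq2 (0.754 and 0.489). Of 3 metallothionein and zinc genes tested, MT1X (-0.68) and MT2A (-0.33) fell and SLC30A1 (0.35) rose, too few for camera. MT2A was not called with median-of-ratios scaling (adjusted p = 0.171), a pseudocount of 0.25 (0.103), edgeR (0.954) or DESeq2 (0.919).

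In SUDHL6, 3424 genes were higher and 5273 lower (68.1% of those tested), 909 and 2069 of them by at least 2-fold. The largest increases were in SLAMF7, from 1.457 ± 0.44 to 188.6 ± 109 CPM (6.14, SE 0.389, adjusted p = 2.61e-09), ATF3 (4.86), RGS1 (4.71), SLC7A11 (4.66), the chemokine receptor gene CCR7 (4.63, 1.083 ± 0.221 to 61.35 ± 47.5 CPM) and GABARAPL1 (4.61). Without treated SUDHL6 replicate 1, CCR7 was at 4.05. The largest decreases were in CUX2, from 206 ± 55.2 to 14.06 ± 4.55 CPM (-3.79), WNT10A (-3.68), LRRC20 (-3.55), ESPNL (-3.54), CHDH (-3.54) and SIT1 (-3.49). The ATF4 (21 of 26 higher, median 1.35), NRF2 (14 of 16, 2.29), heat shock (10 of 15, 1.38), immediate early (16 of 24, 1.12) and histone lists (10 of 12, 1.13) rose, with camera adjusted p from 4.22e-09 to 0.000362. The MYC target (18 of 18 lower, median -1.15), DNA replication (20 of 22, -1.44), mitosis (22 of 22, -1.59), B cell receptor (19 of 21, -1.29) and oxidative phosphorylation lists (22 of 36, -0.37) fell, with adjusted p from 5.34e-06 to 0.00712. With an estimated correlation all of these had an adjusted p from 0.309 to 0.712, and oxidative phosphorylation was also lost with median-of-ratios scaling (median -0.20, adjusted p = 0.0556).

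The PRC1 and BCOR list was higher in SUDHL6 (10 of 23 higher, 4 lower, median 0.19, or 0.35 with median-of-ratios scaling, adjusted p = 0.048; adjusted p = 0.471 with an estimated correlation). That call was lost with the replicate block, whose numbers pair the samples in this line (0.0518), without SUDHL6 DMSO replicate 3 (0.0754), treated SUDHL6 replicate 2 (0.0593) or 3 (0.0964) or SUDHL4 DMSO replicate 1 (0.05), without both shallow libraries (0.143) and with only this line in the fit (0.0567). The block made calls of the germinal centre (13 of 21 lower, median -0.71, adjusted p = 0.0447) and fatty acid lists (7 of 10 lower, median -0.64, adjusted p = 0.0447), and of the aryl hydrocarbon receptor (3 of 6 higher, adjusted p = 0.0411) and FOXO lists (7 of 12 higher, adjusted p = 0.0426). With an estimated correlation and no block these lists had an adjusted p of 0.698, 0.594, 0.439 and 0.482. BCL6 targets were not called in SUDHL6 (11 of 22 higher, 6 lower, median 0.40, adjusted p = 0.0682), nor was glycolysis and hypoxia (8 of 20 higher, 5 lower, median 0.09, adjusted p = 0.316). With median-of-ratios scaling 4232 genes were higher and 4447 lower in SUDHL6 (48.8% higher against 39.4%), and with edgeR 4388 and 4313.

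In Farage, 3246 genes were higher and 5939 lower (71.9%), 942 and 2431 by at least 2-fold. HMOX1, the heme-degrading oxygenase, rose from 43.83 ± 1.96 to 1632 ± 101 CPM (5.19, SE 0.271, adjusted p = 1.83e-10), next to DNAJB4 (5.27), HSPA1B (4.98), OSGIN1 (4.95), KLHL21 (4.66) and the TRAIL receptor gene TNFRSF10D (4.62, 5.783 ± 0.925 to 164.5 ± 3.11 CPM). NAPSB (-4.02), SNX22 (-3.80), CUX2 (-3.72), MPEG1 (-3.59, 482.4 ± 15.6 to 39.13 ± 1.49 CPM), IKBKE (-3.47) and MZB1 (-3.26) fell most. Rising lists were ATF4 (23 of 26 higher, median 1.77), heat shock (15 of 15, 1.99), glycolysis and hypoxia (19 of 20, 1.28), immediate early genes (18 of 24, 1.30) and NRF2 (13 of 16, 2.11), with adjusted p from 5.03e-10 to 1.68e-06 and 0.309 with an estimated correlation. The aryl hydrocarbon receptor (3 of 6, adjusted p = 0.0199) and histone lists (6 of 12, 5 over the list alone, adjusted p = 0.022) rose too, with an adjusted p of 0.343 and 0.501 with an estimated correlation. Both were lost with median-of-ratios scaling (0.0556 and 0.0881). Their medians were 0.71 and 0.37 at the deposited scale and 0.84 and 0.42 with that scaling.

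Farage had more falling lists. Of 21 interferon response genes 19 fell (median -1.05, adjusted p = 0.000384; adjusted p = 0.124 with an estimated correlation), as did 16 of 23 antigen presentation genes (-1.02, 0.0186) and 15 of 20 NF-kB genes (-1.26, 0.0199), with an adjusted p of 0.462 and 0.522 with an estimated correlation. The NF-kB call was lost with a pseudocount of 0.25 (0.0542) and at a mean CPM of at least 5 (0.0944). Oxidative phosphorylation (30 of 36 lower, median -0.60, adjusted p = 9.37e-05), B cell receptor signalling (17 of 21, -1.32, 0.00384), DNA replication (20 of 22, -1.16, 0.013), mitosis (19 of 22, -1.71, 0.0143) and MYC targets (13 of 18, -0.41, 0.0169) fell, with adjusted p from 0.511 to 0.772 with an estimated correlation. MYC targets were lost with median-of-ratios scaling (-0.17, adjusted p = 0.0771), and the median of oxidative phosphorylation was then -0.36. With that scaling 4285 genes were higher and 4750 lower (47.4% higher against 35.3%), and with edgeR 4322 and 4838.

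In SUDHL4, 3102 genes were higher and 5894 lower (70.5%), 957 and 2556 by at least 2-fold. MYC fell from 379.4 ± 47.2 to 26.61 ± 0.741 CPM (-3.78, SE 0.0985, adjusted p = 4.45e-13), next to PTPN6 (-3.79), FAM111B (-3.58), LZTS1 (-3.53), MAB21L1 (-3.50) and PFAS (-3.46). CRIM1 (5.43, 6.286 ± 10.9 to 116.6 ± 6.39 CPM), SLC7A11 (4.57), PPP1R15A of the integrated stress response (4.46), ATF3 (4.20), RGS1 (4.19) and SLAMF7 (4.15) rose most. Without SUDHL4 DMSO replicate 3, which carries most of the baseline of CRIM1, these were 6.85 for CRIM1, 5.53 for SLC7A11, 5.24 for PPP1R15A, 4.97 for ATF3 and 4.85 for RGS1. CRIM1 was at 4.70 without replicate 1 and 4.72 without replicate 2 of that group. The ATF4 (20 of 26 higher, median 1.54), glycolysis and hypoxia (17 of 20, 0.98), NRF2 (11 of 16, 1.61), heat shock (10 of 15, 11 over the list alone, 1.45), histone (8 of 12, 0.47) and aryl hydrocarbon receptor lists (5 of 6, 1.18) rose, with adjusted p from 3.42e-09 to 0.00327 and, with an estimated correlation, from 0.309 to 0.444. DMSO replicate 3 of this line held a median of 13.38% of the change of the 223 genes raised at least 4-fold, against 0.18% and -0.01% for replicates 1 and 2. Without it 2999 genes were higher and 5744 lower. MYC targets (18 of 18 lower, median -1.87, adjusted p = 1.96e-06), DNA replication (20 of 22, -1.98, 0.000207), oxidative phosphorylation (30 of 36, -0.52, 0.00193) and B cell receptor signalling (17 of 21, -1.11, 0.0135) fell, with adjusted p from 0.309 to 0.594 with an estimated correlation. With median-of-ratios scaling the median of oxidative phosphorylation was -0.22.

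Immediate early genes were called higher in SUDHL4 (11 of 24 higher, 6 lower, median 0.20, adjusted p = 0.0192; adjusted p = 0.591 with an estimated correlation). That call was lost with median-of-ratios scaling (median 0.41, adjusted p = 0.0874) and without treated SUDHL4 replicate 2 (0.0512). FOXO targets were called higher (7 of 12, median 0.81, adjusted p = 0.048; adjusted p = 0.462 with an estimated correlation). This was lost in 11 other alternatives (adjusted p from 0.0502 to 0.118). The single libraries whose removal ended it were SUDHL6 DMSO replicates 1 (0.0521), 2 (0.0535) and 3 (0.0678), SUDHL4 DMSO replicate 1 (0.0533) and treated SUDHL4 replicate 3 (0.0502). Mitosis was not called (18 of 22 lower, 19 over the list alone, 1 higher, median -1.28, adjusted p = 0.0794). It was called without treated SUDHL6 replicate 1 (3.76e-05) or 3 (0.0354), with only this line in the fit (0.000184), with no filter (0.0119) and with median-of-ratios scaling (0.0256). With that scaling the homeobox list (14 of 23 lower, adjusted p = 0.0319, against 0.067) and the ribosomal protein list (median 0.33 upward, adjusted p = 0.00674) were called too. The same scaling gave 4376 genes higher and 4609 lower (48.7% higher against 34.5%), and edgeR gave 4588 and 4542.

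The calls of the lines overlapped. Of 11774 genes called in at least 1 line, 1883 were higher and 3618 lower in all 3, against 211 and 1132 from independent lists. With median-of-ratios scaling 2727 were higher and 2648 lower in all 3. SUDHL6 and Farage shared 2309 higher and 4139 lower genes (870 and 2453 from independent lists), SUDHL4 and Farage 2214 and 4503 (789 and 2741), and SUDHL6 and SUDHL4 2349 and 4244 (832 and 2434), each with a one-sided Fisher's exact p of 1e-300, the smallest written. That test takes genes as independent units, which they are not, so its p does not measure the spread between samples. Genes called in opposite directions numbered 435, 432 and 325 for these pairs. Fold changes correlated across genes, which are not independent replicates, with Pearson's r of 0.737, 0.736 and 0.776 and Spearman's rho of 0.734, 0.741 and 0.778. Genes called in 1 line and not in the others numbered 982 higher and 1534 lower, which does not show that the lines differ there.

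The difference of the response was tested directly. The change of BCL6 in SUDHL4 lay below that in Farage (difference -1.13, SE 0.204, adjusted p = 0.000385) and that in SUDHL6 (0.74 for SUDHL6 minus SUDHL4, adjusted p = 0.0104). BCOR differed in each pair (SUDHL6 minus Farage 2.23, adjusted p = 6.85e-07; SUDHL4 minus Farage 1.56, adjusted p = 2.17e-05; SUDHL6 minus SUDHL4 0.67, adjusted p = 0.0202). CBX8 differed between SUDHL6 and both others (0.96, adjusted p = 0.00493, and 0.79, adjusted p = 0.0173). EZH2 had no called difference (adjusted p = 0.273 for any). MYC fell by 3.78 in SUDHL4, by 1.45 in SUDHL6 (343 ± 22.2 to 124.9 ± 9.26 CPM) and by 0.27 in Farage (177.8 ± 10.3 to 147.6 ± 17.7 CPM; -0.029 with median-of-ratios scaling). This is a difference of -3.51 between SUDHL4 and Farage (SE 0.139, adjusted p = 7.53e-11). HSPA1A rose by 4.60 in Farage (6.112 ± 0.593 to 171.3 ± 11.1 CPM) and 0.64 in SUDHL4 (difference -3.96, adjusted p = 2.21e-11), and it shares reads with HSPA1B. In SUDHL4 DMSO it was at 0.0897 CPM, where the pseudocount makes a fold change smaller. The size of this difference therefore depends on that low level. HMOX1, which rose in Farage and SUDHL6 (4.04), was at 0.4971 ± 0.0436 and 0.7251 ± 0.172 CPM in SUDHL4 (0.20, adjusted p = 0.535).

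Most other genes with the smallest p were expressed in 1 line. The interferon-inducible XAF1 and GBP4 and the locus UNQ6494 fell in Farage (19 ± 0.964 to 1.533 ± 0.201, 58.86 ± 2.34 to 7.706 ± 0.965 and 24.72 ± 2.36 to 2.881 ± 0.108 CPM) and were below 0.1 CPM in SUDHL6 and SUDHL4. Their differences between SUDHL6 and Farage (2.97, 2.79 and 2.73) therefore set a fall against a gene near 0, and edgeR (adjusted p = 0.852, 1 and 1) and DESeq2 (0.198, 0.151 and 0.129) did not call them. SLA (18.91 ± 1.53 to 1.19 ± 0.407 CPM), EHD3 (22 ± 3.1 to 1.219 ± 0.338) and RGNEF (14.76 ± 2.41 to 1.135 ± 0.134) fell in SUDHL4 and were near 0 in SUDHL6 (differences 3.15, 3.34 and 2.89), again with no call by edgeR (adjusted p = 0.705, 0.775 and 0.123). The difference was called for 4696 genes between SUDHL6 and Farage (36.8%; 2767 above 0 and 1929 below), 4775 between SUDHL4 and Farage (37.4%; 2260 and 2515), 4474 between SUDHL6 and SUDHL4 (35%; 2875 and 1599). With median-of-ratios scaling the counts above and below 0 were 2468 and 2337, 2628 and 2369, and 2202 and 2170, so their balance depends on the scaling and turns for SUDHL4 minus Farage. The test of any difference among the lines called 7144 genes (55.9%).

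Most markers of other cell types were under 1 CPM in all groups, with THY1 and DCN in SUDHL4 the highest of the rest. Of 15 T cell markers 9 were under 1 CPM in all groups. Of the 5 tested, 3 rose and 2 fell in the mean (median 0.38, adjusted p = 0.223), with CD28 the highest, at 20.1 CPM in treated SUDHL6 from 0.761 in DMSO. Of 14 myeloid markers 11 were under 1 CPM in all groups, and CD14 (1.24) and CD68 (0.66, at most 14.5 CPM) rose. Of 14 epithelial and fibroblast markers 10 were under 1 CPM in all groups, and the 4 tested fell. THY1 went from 74.17 ± 4.32 to 14.46 ± 1.92 CPM and DCN from 62.27 ± 3.94 to 18.71 ± 1.5 CPM in SUDHL4, and both were under 0.1 CPM in the other lines. In the mean, THY1 was not called with edgeR (adjusted p = 1) or DESeq2 (0.404), and DCN (0.79 and 0.792) and COL1A1 (0.568 and 0.711) changed sign with them, uncalled.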

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

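Of the tests given here, camera on the differences between lines and the shuffles of line labels were chosen after seeing the results.

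The response to the inhibitor differed between lines for 7144 of the 12769 genes tested (55.9%), by a test of the difference itself. Of the 165 named genes 107 differed, a count raised by selection, since some were named for the size of their change or for their difference. Among the genes of the question, BCL6 differed by -1.13 between SUDHL4 and Farage and by 0.738 between SUDHL6 and SUDHL4. The Polycomb gene CBX8 differed by 0.959 between SUDHL6 and Farage and by 0.789 between SUDHL6 and SUDHL4. BCOR differed by 2.228 between SUDHL6 and Farage, 1.562 between SUDHL4 and Farage and 0.666 between SUDHL6 and SUDHL4. MYC, a driver of growth, differed by -3.505 between SUDHL4 and Farage, and the heat shock gene HSPA1A by -3.961. For these genes both lines expressed the gene in DMSO, except that HSPA1A was at 0.0897 CPM in SUDHL4 DMSO.

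Other named differences set a fall in 1 line against a gene near 0 in the other. These were UNQ6494 (2.725 for SUDHL6 minus Farage and 2.742 for SUDHL4 minus Farage), XAF1 (2.965) and GBP4 (2.786) for SUDHL6 minus Farage, and SLA (3.145), EHD3 (3.34) and RGNEF (2.894) for SUDHL6 minus SUDHL4. RGNEF was also called in opposite directions in SUDHL4 (-2.87) and Farage (0.32, from 0.096 to 0.369 CPM), a difference of -3.198.

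Interferon response genes fell in Farage (median -1.05, adjusted p = 0.000384; adjusted p = 0.124 with an estimated correlation) and were not called as a list in SUDHL6 (-0.02, adjusted p = 0.815) or SUDHL4 (-0.04, adjusted p = 0.724). The median difference from Farage was 0.81 in SUDHL6 (adjusted p = 1.61e-06; adjusted p = 0.00324 with an estimated correlation) and 0.98 in SUDHL4 (adjusted p = 2.73e-08; adjusted p = 0.00194 with an estimated correlation). In DMSO the list lies higher in Farage (median 1.67), and members such as XAF1 are near 0 in the other lines, where they have no room to fall. With both settings of the correlation this list was called, and 19 of 90 list differences were called at the preset correlation. Glycolysis and hypoxia genes rose in Farage and SUDHL4 (adjusted p = 0.309 with an estimated correlation in each) and were not called in SUDHL6 (adjusted p = 0.316). The median difference of SUDHL6 was -1.08 from Farage (adjusted p = 1.28e-08) and -0.97 from SUDHL4 (adjusted p = 1.59e-08; adjusted p = 0.466 with an estimated correlation for each). NF-kB genes fell in Farage (adjusted p = 0.0199) and were not called in SUDHL6 (0.699) or SUDHL4 (0.814). The Farage call was lost with an estimated correlation (0.522), a pseudocount of 0.25 (0.0542) and a mean CPM of at least 5 (0.0944). In DMSO the NF-kB list too lies higher in Farage (median 3.73, 18 of 20 higher and 0 lower). Less room to fall in the other lines therefore cannot be set aside for it. The median difference from Farage was 0.89 in SUDHL6 (adjusted p = 0.0147; adjusted p = 0.854 with an estimated correlation) and 0.87 in SUDHL4 (adjusted p = 0.000597; adjusted p = 0.713 with an estimated correlation). MYC targets were lower in SUDHL6, SUDHL4 and Farage (adjusted p = 0.309, 0.309 and 0.589 with an estimated correlation; in Farage 0.0771 with median-of-ratios scaling). The median difference from Farage was -0.48 in SUDHL6 (adjusted p = 0.00175; adjusted p = 0.854 with an estimated correlation) and -0.55 in SUDHL4 (adjusted p = 2.93e-06; adjusted p = 0.599 with an estimated correlation). That of SUDHL6 from SUDHL4 was 0.56 (adjusted p = 0.00617; adjusted p = 0.869 with an estimated correlation).

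The remaining list differences called at the preset correlation were lost with an estimated correlation, with adjusted p from 0.466 to 0.927. From Farage, the heat shock list had a median difference of -0.82 in SUDHL6 (adjusted p = 4.28e-05) and -0.82 in SUDHL4 (0.021). Immediate early genes were at -0.61 (0.0118) and -0.72 (0.00872), and p53 genes at 0.58 (0.00141) and 0.52 (0.0497). Antigen presentation (0.52, adjusted p = 0.00617) and DNA replication (-0.79, 0.0204) were called for SUDHL4 minus Farage alone. For SUDHL6 minus SUDHL4 these were the NRF2 (0.62, adjusted p = 0.0417) and unfolded protein response lists (-0.24, 0.0122).

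By number, 4696 genes differed between SUDHL6 and Farage, 4775 between SUDHL4 and Farage, 4474 between SUDHL6 and SUDHL4, and 7144 among the lines. With each line centred and the line labels shuffled among treated and among DMSO libraries, which keeps the shared response, only the real one of 100 splits gave as many. The highest of the other splits gave 1910, 1062, 2195 and 626 genes, which argues against a random grouping of these libraries for these counts. The shuffles leave the pairing of SUDHL6 aside and take all libraries as equally variable. They cannot speak to chance between cultures, since the replicates may be technical. With treatment labels shuffled within lines, a random grouping is argued against for the mean of the lines too, with the same limit. The real split called 10718 genes and the highest other 4504, or 3211 among the 41 splits that part the 3 SUDHL6 pairs. For the number of lists called in the mean a random grouping stays open: the real split gave 13, the others a median of 9 and at most 17, and 24 of 100 splits gave as many.

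In a single line the 6 libraries make 10 splits, which cannot give a share under 0.05. Of these only the real 1 called 9185 genes in Farage and 8996 in SUDHL4, and the highest other called 0 with limma in each. In SUDHL6 the real split called 8697 and the highest other 466. Among the splits that part all 3 numbered pairs, as the real one does, the highest other called 1 gene, while the rest keep 2 pairs together.

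Reads outside the listed genes, which count in the divisor of the CPM and in no gene, took a larger share after treatment, by 2.27 percentage points in the mean of the lines (exact permutation p = 0.001, 8000 assignments). The share went from 21.93 ± 0.65 to 24.67 ± 0.68% in SUDHL6 (exact p = 0.1), 20.77 ± 1.05 to 23.48 ± 1.61% in Farage (exact p = 0.1) and 19.74 ± 0.73 to 21.1 ± 1.19% in SUDHL4 (exact p = 0.2), where 0.1 is the smallest p that 20 assignments give. Which sequences these reads come from was not analysed here.

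More genes fell than rose at the deposited scale. With median-of-ratios scaling 47.1% of the genes called in the mean were higher, but that scaling centres the typical gene (median -0.051), which fixes a near-even split. Scaling to all reads as the cause therefore cannot be told apart from a real excess of falling genes. Few genes taking most of the gained reads are argued against as its cause: without the 50 genes of largest gain, which hold 19.9% of it, the median change was -0.17, against -0.212 with them. Whether total RNA per cell changed cannot be read from these data, and no biological explanation was tested.

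The ATF4, NRF2 and heat shock lists rose in all 3 lines. Heat shock rose less in SUDHL6 and SUDHL4 than in Farage, and NRF2 more in SUDHL6 than in SUDHL4. These differences, given above, were lost with an estimated correlation (adjusted p = 0.854 and 0.927 for heat shock, 0.907 for NRF2). With the trend on GC content and transcript length removed, all 9 tests stayed past the threshold and the smallest ratio of corrected to uncorrected median was 0.992. The removal also recentres each library, so these ratios do not measure the trend alone. In Farage the heat shock median was 1.99 as deposited, 2.23 with median-of-ratios scaling and 1.97 corrected. The corrected medians, from 1.4 to 2.46, still argue against that bias as the source of the rise. With median-of-ratios scaling 9 of 9 tests passed (highest adjusted p 0.000217, smallest median 1.5). That scaling moves all genes of a library nearly alike, and camera sets a list against the other genes. These tests could therefore hardly fail and do not decide on the scaling. The medians show only that the typical member still rose at that scale. The tests pass at the preset correlation alone. Treatment is the biological explanation the design gives, with effects of the compound beyond BCL6 or of 10 µM as such left open, since there is no other dose or compound.

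SUDHL4 DMSO replicate 3 lay nearer to the treated libraries than its partners. A swapped label is argued against, since it held a median of 16.22% (95% interval 15.57 to 16.83) of the treated-minus-DMSO change. For a mixture with treated cells or RNA the implied share was 13.38% over 223 raised and 18.91% over 495 lowered genes, a gap of -5.53 points with intervals apart. The bound set beforehand counted the spread over genes and left out that between libraries, where replicates 1 and 2 themselves give -2.49 and 1.44 points, so a mixture stays open. The design names no biological difference for this library, so none was tested.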

How the results depend on the processing

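The fit without both shallow SUDHL6 libraries was chosen after seeing the data. Of the named genes' values, the direction and side of the threshold were the same in 204 of 205 with a pseudocount of 0.25, 204 with no filter, 177 of 177 at a mean CPM of at least 5, 199 of 205 with median-of-ratios scaling, 204 with the replicate block, 54 of 57 with only the compared lines, 180 of 205 with edgeR and 180 of 201 with DESeq2. With edgeR 20 were no longer called and 3 newly called, and with DESeq2 13 and 4.

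Genes expressed in 1 line reversed in the mean on recovered reads. DCN went to 0.79 with edgeR and 0.792 with DESeq2, COL1A1 to 0.568 and 0.711, and with DESeq2 HOXA10 to 0.048 and CD3E to 0.016. None of these was called (adjusted p from 0.271 to 1). In the lines that did not express them, DCN was at most 0.0597 CPM and COL1A1 at most 0.0993 CPM. There the pseudocount of 1 keeps the fold change of the main test near 0. The tests on recovered reads give these lines equal weight in the mean without that pseudocount, so the reversed signs rest on almost no reads. TNFAIP2, XAF1, IFIH1, CYP1B1, IRS2, TRAT1, THY1, MT2A, RPL41 and RPL35, among others, lost their call in the mean with edgeR, DESeq2 or both.

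Requiring a fold of at least 1.5 left 2099 higher genes in SUDHL6, 1962 in Farage, 1973 in SUDHL4, 1871 higher and 4079 lower in the mean, and 1909 above 0 in SUDHL6 minus SUDHL4. This setting keeps fewer genes by construction. With only the compared lines in the fit, 3496 genes were above 0 in SUDHL4 minus Farage, against 2260. The main fit shares its spread with SUDHL6, whose replicates agreed least. Without treated SUDHL6 replicate 1 the count was 2648, and without both shallow SUDHL6 libraries 2829, so it depends on that shared spread. The fit of only the compared lines gives no value for the mean of the lines or for any difference among them. The other counts of genes stayed within 1.5 times their value under each setting run for them. The overlap of all 3 lines was not counted with edgeR, DESeq2 or the fold of at least 1.5.

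With an estimated correlation 0 lists were called higher and 0 lower in each line and in the mean, against 4 to 8 at the preset value. That setting changes both the correlation and the degrees of freedom of the test, so the loss cannot be laid to correlation alone. The interferon list was lost in Farage although its estimated correlation (-0.007) lies below the preset 0.01. At a mean CPM of at least 5, where fewer genes are tested, 5 lists were called higher in SUDHL4 and 5 in the mean, against 8. Median-of-ratios scaling ended 7 list calls and made 4, and no filter ended 1 and made 6.

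The replicate block gave 3596 higher and 5541 lower genes in SUDHL6, 3386 and 6221 in Farage, 3295 and 6147 in SUDHL4, and 3962 and 7045 in the mean. Beside the SUDHL6 lists given above it made calls of EZH2 (adjusted p = 0.0217) and mitosis (0.0334) in SUDHL4, where the numbers do not pair the samples.

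Leaving out 1 library at a time gave these lowest and highest counts of higher and lower genes: 3216 to 3500 and 4934 to 5413 in SUDHL6, 3033 to 3352 and 5559 to 6148 in Farage, 2885 to 3235 and 5534 to 6086 in SUDHL4, and 3771 to 3901 and 6730 to 6956 in the mean. For the differences they were 2369 to 3284 and 1614 to 2274 (SUDHL6 minus Farage), 1910 to 2648 and 2176 to 2983 (SUDHL4 minus Farage), 2385 to 3566 and 1306 to 1919 (SUDHL6 minus SUDHL4) and 6462 to 8049 (any). Genes called in all 3 lines ranged from 1798 to 1945 higher and 3426 to 3759 lower. Lists called higher and lower were 5 to 8 and 5 to 6 in SUDHL6, 7 and 8 in Farage, 7 to 8 and 4 to 5 in SUDHL4, and 7 to 8 and 5 in the mean. Without both shallow SUDHL6 libraries 3350 genes were higher and 5437 lower in SUDHL6, and 3894 and 7081 in the mean.

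Some lists not called in SUDHL6 were called there when a library was left out. The aryl hydrocarbon receptor list (adjusted p = 0.0502 with all) was called without SUDHL6 DMSO replicate 1 (0.0466) or 2 (0.0425), treated SUDHL6 replicate 3 (0.0323), SUDHL4 DMSO replicate 2 (0.0488) or 3 (0.0435) and treated SUDHL4 replicate 2 (0.0488) or 3 (0.0476). FOXO targets were called without SUDHL6 DMSO replicate 1 (0.0446) or treated replicate 3 (0.0354), germinal centre genes without treated replicate 2 (0.0233), antigen presentation without treated replicate 1 (0.0492), fatty acid synthesis without DMSO replicate 1 (0.0446) and ribosomal proteins without treated replicate 2 (0.0305). In SUDHL4 ribosomal proteins were called without treated SUDHL4 replicate 3 (0.0292). BCL6 targets were called in SUDHL6 without both shallow libraries (0.0425).

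Depth limits low values most in SUDHL6 replicate 3, where 3 reads are 0.362 CPM, against 0.095 CPM in the deepest library.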

Other observations

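The comparison of the lines in DMSO was chosen after seeing the data.

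The plasma cell (adjusted p = 0.91), germinal centre (0.294) and BCL6 target lists (0.0985) were not called in the mean. Of single regulators, 6 outside the naming rule were chosen after their values were seen, so they stand for no group. IRF4, a factor of plasma cell and activated B cell fate, rose in SUDHL6 (2.10, 56.25 to 214.6 CPM), Farage (1.69, 334.9 to 1081 CPM) and SUDHL4 (2.06, 0.9274 to 6.836 CPM). XBP1, of the secretory programme, rose by 1.33 in the mean (SE 0.117, adjusted p = 1.49e-08), and PRDM1, a repressor that BCL6 silences in the germinal centre, by 1.30 in Farage (2.827 to 8.432 CPM) and by 0.63 in SUDHL6, where it reached 0.5607 CPM, and was not called in SUDHL4 (0.16, adjusted p = 0.255). CDKN1A, an inhibitor of the cell cycle, rose in each line (2.68, 1.28 and 1.77). GPR183 and ID2 rose in SUDHL6 (2.65 and 1.89) and SUDHL4 (2.03 and 1.85) and were not called in Farage (-0.43 and 0.09), with a called difference between SUDHL6 and Farage (3.07, adjusted p = 0.000126, and 1.80, adjusted p = 0.00106).

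In DMSO, Farage differed from the mean of the other 2 lines in several lists, of which the interferon, NF-kB, p53 and immediate early lists also had a called difference of response to SUDHL6 and to SUDHL4 at the preset correlation. With an estimated correlation that held for interferon alone (adjusted p = 0.00324 and 0.00194; 0.466 to 0.9 for the others). NF-kB and CD40 response genes were higher in Farage (18 of 20 higher, none lower, median 3.73, adjusted p = 1.91e-09; adjusted p = 0.0522 with an estimated correlation). Interferon response genes were higher too (15 of 21 higher, 1 lower, median 1.67, adjusted p = 6.08e-06; adjusted p = 0.00431 with an estimated correlation), as were BCL6 targets (15 of 22 higher, 3 lower, median 0.97, adjusted p = 0.00688; adjusted p = 0.0522 with an estimated correlation), p53 response genes (16 of 24 higher, median 0.97, adjusted p = 0.00201; adjusted p = 0.262 with an estimated correlation) and immediate early genes (17 of 24 higher, median 1.53, adjusted p = 0.000427; adjusted p = 0.498 with an estimated correlation). Ribosomal protein genes (62 of 73 lower, median -0.78, adjusted p = 2.89e-09; adjusted p = 0.773 with an estimated correlation) and histone genes (11 of 12 lower, median -0.74, adjusted p = 0.00338; adjusted p = 0.429 with an estimated correlation) were lower. In all, 4342 genes were higher and 4610 lower in Farage DMSO.

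The prediction set beforehand was that a block of transcription elongation would lower long genes relative to short ones. The highest of the 3 Spearman correlations across genes of log2 fold change with genomic span was 0.102 (0.059 in SUDHL6, 0.095 in Farage and 0.102 in SUDHL4), the opposite sign. The shortest genes, up to 11.8 kb, had medians of -0.22, -0.35 and -0.33, and the longest, from 70.5 kb, -0.06, -0.12 and -0.08. The predicted fall of long genes relative to short ones was therefore not seen. RNA levels at 12 h, the only time sampled, also depend on RNA decay, so these data do not decide on such a block.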
